A study of Mus musculus with 768 samples.

How the data were processed

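Single cells carrying the Nestin:GFP reporter, green fluorescent protein driven by regulatory sequence of the neural stem cell gene Nes, were sorted from the dentate gyrus of 8 male mice into wells. Per the labels, 4 mice had received a miR-132 mimic and 4 a negative control oligonucleotide, mixed with lipofectamine 2000, in weekly injections over 5 weeks. Each cell was made into a full-length cDNA library with Smart-seq2, a plate method without molecular identifiers, and sequenced on a NextSeq500, per the labels' protocols. The values are whole-number read counts per gene, as deposited by the authors in 1 table of 32679 genes and 768 wells. Per the submitters' processing notes, FastQC, STAR, Subread, featureCounts 1.5.1 and Seurat 2.3.1 were used with the mouse build mm10. How each tool was set is not given in the sources used here. Smart-seq2 does not mark strand, so reads of a gene and of an antisense partner cannot be told apart.

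The labels give 2 maps from well names to mice. In the map used here, the well names written in a sample's description belong to the mouse of that sample. Each well name stands in the descriptions of 4 samples, and for all 768 names those samples share 1 mouse. In the other map, a well belongs to the sample that has its name as title. The maps agree on the mouse of 96 wells and on the treatment of 384 wells. The description map was chosen from the labels before the data were examined, and the title map is an alternative for each result. Class counts were compared between mice with a chi-square statistic and 100000 permutations of the mouse labels, run after the first treatment tests although planned before them. Labels of the title map were permuted within runs of index numbers, and labels of the description map over all cells. Near-empty wells were counted below 5000 counts, after a first limit of 1000, both set after seeing the data.

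Wells were kept with at least 50000 counts, at least 1000 genes with a count and at most 15% of counts on mitochondrially encoded genes. This left 674 of 768 wells. Counts per 10000 on a log scale, 2000 variable genes, 20 principal components and 15 neighbours entered Leiden clustering at resolution 1 (Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Clusters were named as "like" a cell type from marker lists fixed before the data were examined. No doublet caller was run on sorted single cells. Of 658 cells in named classes, 1 had at least 50% of the markers of another class at 50 CPM or more. A cluster of 16 wells with more than 6000 genes each was left unnamed, a limit set after seeing the data. These wells stay in the sums over all kept cells and in no class.

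By the check planned for cluster names, the 10 genes of highest fold, 2 clusters had no marker of their own class and 1 of another. These were cluster 1 (oligodendrocyte-like) and cluster 6 (astrocyte-like), the latter with the stem cell marker Hopx. By difference of log means, a ranking added after seeing this, both had more of their own. Oligodendrocyte-like cells are therefore given both together and as clusters 1 and 2. Clusters 6 and 8, the astrocyte-like cells, had too few cells per mouse for a gene test by number, so only their sum is tested.

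The mouse is the replicate. Raw counts were summed per mouse over all kept cells and over each class with at least 5 cells in at least 3 mice of each treatment. Genes with a count in at least 10% of cells that passed edgeR's filterByExpr were tested with edgeR 4.0.16 (quasi-likelihood test, TMM, sort date as covariate, two-sided, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Folds are log2 mimic over control from the edgeR fit, for which no prior count was set, given with standard errors. Gene lists with at least 5 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, then at an estimated correlation, and with fry, adjusted over the lists of each cell set. These list tests used log2 CPM with a prior count of 2. Shares of cells and quality measures were compared with exact permutation tests over the 70 splits of 4 mice against 4, whose smallest p is 0.0286. On simulated counts with 200 changed genes in all kept cells (8822 genes), the edgeR test found 26% of 2-fold and 86% of 4-fold changes. The same test found 22% and 50% in oligodendrocyte-like cells (7450 genes). In astrocyte-like (7480 genes), endothelial-like (5971 genes) and pericyte-like cells (5105 genes) it found 14%, 6% and 14% of 16-fold changes.

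Sites for miR-132-3p (UAACAGUCUACAGCCAUGGUCG) were searched in the longest 3' UTR of each gene in GENCODE M21. The site is GACTGTTA over 8 bases, and GACTGTT over 7 bases. UTRs ran from the annotated stop codon to the transcript end, with the stop codon found at its place in 55063 of 55063 transcripts and a 3' UTR for 21153 genes. The median log2 fold of genes with a site was set against the median of site-free genes weighted to the same mix of 20 UTR length bins and 5 expression bins, with 100000 permutations of site labels within bins. Alternatives of this test used 1000.

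The named genes are the 10 of smallest p in each cell set, a fixed set of lineage genes and published miR-132 targets, and the 4 members of smallest p in each list that passed camera. Some of these genes are not reported here, and counts and medians of lists and classes include them. Gene coordinates are from GENCODE M21, on the same mouse build. Alternatives were DESeq2 1.42.0, other scalings, low-count filters, covariates, cell filters, clusterings, cells thinned to 50000 counts, limma on mean log2(CPM + 1), the title map, and leaving out each mouse in turn. The looser cell filter took 10000 counts and 500 genes, and the stricter one 100000 counts and 2000 genes. Figures were drawn with matplotlib 3.10.9. Reads are not independent molecules here. A floor of 3 counts over the tested mice of a group, used where a group had no count, therefore covers counting error only. It sets no lower limit on a fold.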

Results

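Gene counts were obtained from single cells of the dentate gyrus, the part of the hippocampus in which neurons are born in adult rodents. The cells were sorted for the Nestin:GFP reporter, which marks neural stem cells and other cells that use the Nes promoter. The series text writes "AD" before the tissue without saying whether it stands for adult or for Alzheimer's disease. The 8 male mice were 2 months old and received 150 pmol of oligonucleotide in 3 µl once a week for 5 weeks. Control mice are numbered 1, 3, 5 and 7, and mice given the miR-132 mimic, a synthetic copy of the microRNA, are 2, 4, 6 and 8. Mice 1 to 4 were sorted on 17 April 2018 and mice 5 to 8 on 19 April 2018, so each date holds 2 mice of each treatment. The labels report 94 cells sorted per mouse, and the table holds 96 wells per mouse. Of 768 wells, 674 were kept (74 to 92 per mouse), with a median of 646630 counts and 2743 genes. Summed over kept cells, a mouse had 4.39e+07 to 6.69e+07 counts. Median counts per cell were 648778 ± 70622 (SD, n = 4 mice) with the control oligonucleotide and 663596 ± 85556 (n = 4) with the mimic (exact permutation p = 0.743). Median genes per cell were 2686 ± 246 and 2743 ± 193 (n = 4 each, exact permutation p = 0.657). The share of 18S ribosomal RNA was 11.3% ± 1.59 and 10.1% ± 0.864 (exact permutation p = 0.229).

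The first comparison asks which cells the reporter gate held and whether the mimic changed their mix. Oligodendrocyte-like cells, led by the myelin gene Mbp, were the most numerous class with 300 of 674 kept wells. Vascular classes followed, with 107 endothelial-like cells that carried the tight junction gene Cldn5 and 71 pericyte-like cells with Vtn and Rgs5. There were 95 astrocyte-like cells with the glycolytic gene Aldoc and the gap junction gene Gja1, and 39 neuroblast-like cells with Dcx, a microtubule protein of young neurons, and the transcription factor Neurod1. Smaller classes were 17 oligodendrocyte precursor-like, 16 fibroblast-like and 13 smooth muscle-like cells, and 16 further wells, 2 per mouse, held over 6000 genes each. The labels do not say whether those 16 held single cells. They held 10045 to 11362 genes each, against at most 5015 in the other kept wells. Each also had counts of Mbp, Cldn5, Vtn and Aldoc (means 9425, 1004, 3852 and 892 CPM). These values argue against single cells in those wells, which stay in the sums and shares over kept cells. No cluster was named for stem cells. The stem cell gene Hopx had a count in 51.6% of astrocyte-like cells and in 1.33% of oligodendrocyte-like cells. Nes itself averaged 377 CPM in pericyte-like, 222 CPM in endothelial-like and 24.7 CPM in astrocyte-like cells. It was lowest of the named classes in oligodendrocyte-like cells, with 18.8 CPM.

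Endothelial-like cells made up 12.2% ± 7.63 of kept cells in control mice and 19.5% ± 8.31 in mimic mice (SD, n = 4 each, exact permutation p = 0.257, adjusted 0.857 over 8 classes). Astrocyte-like cells made up 11.4% ± 4.07 and 16.5% ± 5.68 (exact p = 0.171), and oligodendrocyte-like cells 48.3% ± 14.6 and 41.1% ± 9.23 (exact p = 0.429). Neuroblast-like cells, the neuronal lineage of the gate, made up 7.35% ± 4.54 and 4.33% ± 0.825 (exact p = 0.343). Pericyte-like cells made up 11.5% ± 7.04 and 9.48% ± 3.68 (exact p = 0.657), oligodendrocyte precursor-like cells 2.37% ± 1.25 and 2.69% ± 1.31, fibroblast-like cells 2.40% ± 2.77 and 2.22% ± 1.55, and smooth muscle-like cells 2.06% ± 2.46 and 1.84% ± 1.44 (exact p = 0.714, 1 and 0.971). Control mouse 7 had 22.0% pericyte-like cells, and without it the pericyte-like difference turned to 1.49 points higher with the mimic. No class passed the exact test. Within dates, the astrocyte-like difference was 5.25 percentage points on 17 April and 4.94 on 19 April, and the endothelial-like difference was 6.71 and 7.98. Permuted within dates, a test added after seeing the data, the endothelial-like p was 0.0556, the smallest that the 36 arrangements allow. Neuroblast-like cells differed by -6.42 points on 17 April and by 0.37 on 19 April. Between dates, endothelial-like cells made up 9.66% ± 5.44 and 22.0% ± 5.64 and pericyte-like cells 7.23% ± 1.17 and 13.7% ± 6.02 (17 then 19 April, n = 4 each, exact permutation p = 0.0571 and adjusted 0.152 for each).

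**Figure D1:**
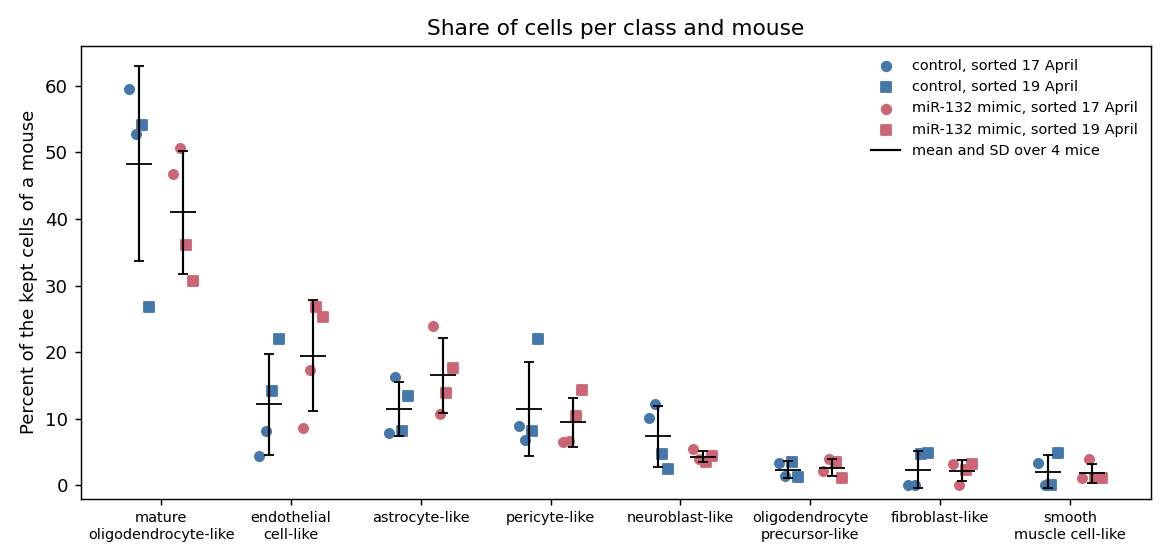
Share of each cell class among kept cells (y axis, percent), one point per mouse, with group means and SD bars for 4 control and 4 miR-132 mimic mice. Endothelial-like cells averaged 12.2% in control and 19.5% in mimic mice, and the points of the groups overlap.

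Within the oligodendrocyte-like class, cluster 1 held 72 cells and cluster 2 held 228. Cluster 1 was led by the immediate early genes Egr2 and Arc, which neurons and glia switch on within minutes of stimulation. It made up 10.5% ± 7.90 of control and 10.8% ± 0.935 of mimic cells (exact permutation p = 0.943), and control mouse 7 had 0 cells of it among 82, which allows a share of up to 3.66%. Cluster 2 made up 37.8% ± 7.48 and 30.2% ± 9.08 (exact p = 0.171), with differences of -2.68 points on 17 April and -12.5 on 19 April. The permutation p within dates, the test added after seeing the data, was 0.0556, again the smallest possible. Of the astrocyte-like clusters, cluster 6 made up 4.81% ± 1.90 and 4.51% ± 4.13 and cluster 8 made up 6.63% ± 4.76 and 12.02% ± 3.94 (exact p = 0.886 and 0.114).

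The second comparison asks which genes the mimic changed in the sorted cells as a whole. Of the 10 genes with the smallest p, 10 had higher means in mimic mice. Sox17, a transcription factor of arterial endothelium, had 125 ± 49.6 CPM in mimic and 39.4 ± 33.7 CPM in control mice (n = 4 each), a log2 fold of 1.91 ± 0.36 (SE). It had a count in 68.2% of endothelial-like cells, whose mean share was also higher with the mimic (19.5% against 12.2%). Agrn and Vwa1, which encode basement membrane proteins, had log2 folds of 1.00 ± 0.22 and 1.18 ± 0.23, and the proteoglycan gene Spock2 had 1.38 ± 0.30. Control mouse 7, with 22.0% endothelial-like cells, had 319 CPM of Spock2 and 305 CPM of Vwa1. Mimic mouse 2, with 8.70% of these cells, had less of both (165 and 287 CPM). Agrn went the other way, with 90.3 CPM in mouse 7 and 151 CPM in mouse 2. Whether the share of endothelial-like cells accounts for these folds was not tested. Id1, an inhibitor of differentiation induced by BMP signals, stood at 350 ± 118 against 137 ± 73.7 CPM, a log2 fold of 1.47 ± 0.33. Log2 folds were 1.07 ± 0.23 for Gpcpd1, 2.04 ± 0.48 for the secretory coat gene Sec24d, 1.5 ± 0.35 for Parva, 3.54 ± 0.85 for Grip2 and 1.25 ± 0.30 for the sphingomyelin synthase gene Sgms1. Grip2 had 4.23, 4.19 and 2.83 without control mouse 1, mimic mouse 2 and control mouse 5. Sox17 (ENSMUSG00000025902.13) lies on chromosome 1 from 4490931 to 4497354, Vwa1 (ENSMUSG00000042116.3) on chromosome 4 from 155768149 to 155774698 and Id1 (ENSMUSG00000042745.9) on chromosome 2 from 152736251 to 152737410 (build mm10, GENCODE M21, all protein-coding).

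None of these genes passed adjustment: edgeR's quasi-likelihood test called 0 of 8822 genes, with a lowest adjusted p of 0.8293. At unadjusted p under 0.05 there were 397 genes, where 441 would be expected by chance. DESeq2 called 12 genes (11 higher, 1 lower), among them Sox17, Sec24d, Vwa1, Parva, Id1 and the interferon-induced gene Rtp4. In 205 genes, 2.32% of those tested, the groups did not overlap, against 2.86% by chance. Without a low-count filter edgeR called 84 of 31899 genes, among them the complement gene C4b, and with wells assigned by sample titles Sox17 had a log2 fold of -1.17.

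The third comparison concerns 19 gene lists fixed before the data were examined. Antigen presentation genes, which load and display peptides on MHC class I, were higher in mimic mice for 7 of 7 measured members, with a median log2 fold of 0.84. H2-D1, an MHC heavy chain, stood at 991 ± 422 against 446 ± 152 CPM, a log2 fold of 1.1 ± 0.27. Its partner B2m had 0.84 ± 0.27, H2-K1 had 0.76 ± 0.29 and the immunoproteasome subunit Psmb8 had 1.89 ± 0.65. Adjusted over the list alone, 7 of 7 passed in edgeR, and over all genes 0 did. The list passed camera with an adjusted p of 3.4e-06, and had an adjusted p of 0.444 with an estimated correlation. Interferon response genes were higher for 11 of 11 members (median log2 fold 0.77), among them Rtp4 (1.76 ± 0.46), the antiviral membrane protein gene Ifitm3 (1.18 ± 0.32), Ifit2 (1.32 ± 0.60) and Ifi27 (0.42 ± 0.18). Psmb8 had 0.95 without mimic mouse 4, and Ifit2 had 2.32 without control mouse 7. Of these, 2 passed adjusted over the list alone, Rtp4 and Ifitm3, and 0 over all genes. The list had a camera adjusted p of 2.31e-05, and an adjusted p of 0.454 with an estimated correlation. Endothelial-like cells, which are rich in MHC class I transcripts, also had a higher mean share in mimic mice (19.5% against 12.2%).

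**Figure D2:**
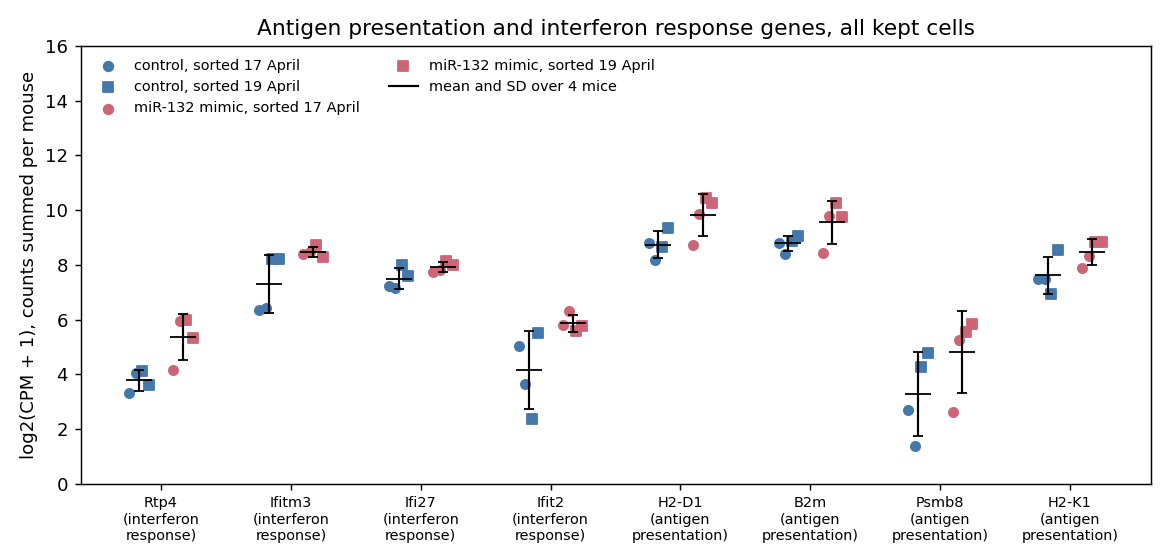
Levels of the named antigen presentation and interferon response genes in all kept cells (y axis, log2(CPM + 1)), one point per mouse, with mean and SD over 4 control and 4 miR-132 mimic mice. Circles are mice sorted on 17 April and squares those of 19 April, and H2-D1 averaged 446 CPM in control and 991 CPM in mimic mice, and mimic mouse 2 lay among the controls with 424 CPM.

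Immediate early and dissociation genes, which cells switch on during stimulation or tissue handling, were higher for 16 of 18 members (median log2 fold 0.48). Dusp1, a MAP kinase phosphatase, had a log2 fold of 0.65 ± 0.22, Ier3 0.94 ± 0.37, the AP-1 factor gene Junb 0.72 ± 0.35 and the mRNA decay factor gene Zfp36 0.61 ± 0.33. Adjusted over the list alone 0 passed, and over all genes 0. The camera adjusted p was 0.000372, and the adjusted p was 0.482 with an estimated correlation. Control mouse 7 had the lowest Dusp1 (189 CPM) and Junb (115 CPM) of the 8 mice and the highest Ier3 (154 CPM). Without it the median log2 fold was 0.17 (camera adjusted p = 0.0389). Endothelial-like cells, whose mean share was higher with the mimic, had more of these transcripts (list mean 3.75 to 6.24 on the log2(CPM + 1) scale in the other 7 mice) than oligodendrocyte-like cells (2.304 to 2.898).

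**Figure D3:**
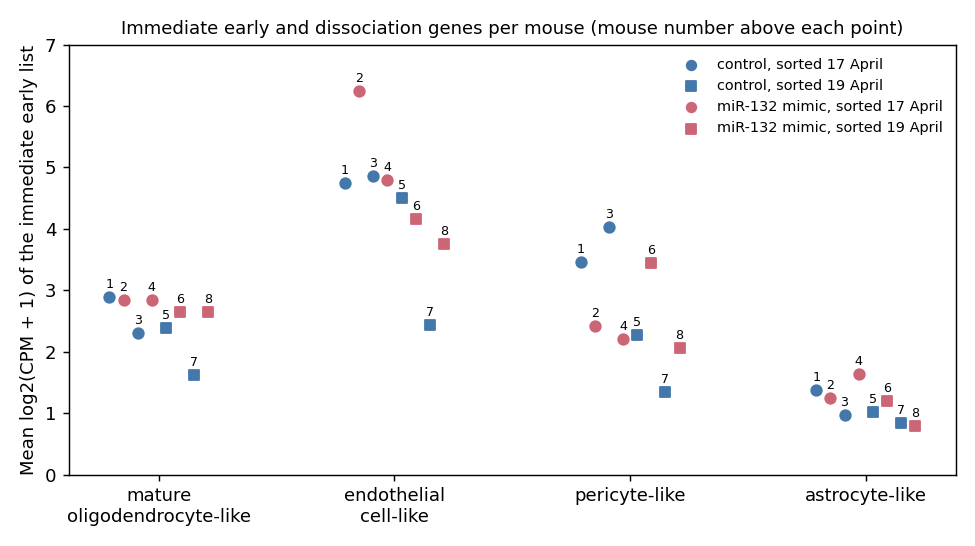
Mean level of the immediate early genes (y axis, mean log2(CPM + 1) of the list) in 4 cell classes (x axis), one numbered point per mouse, for 4 control and 4 miR-132 mimic mice. Control mouse 7 lay lowest of the 8 mice in oligodendrocyte-like (1.62), endothelial-like (2.43) and pericyte-like cells (1.35).

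Stem cell quiescence genes were higher in mimic mice for 18 of 21 members (median log2 fold 0.41), led by Id3, a target of BMP signals (1.22 ± 0.30), the metallothionein gene Mt1 (0.66 ± 0.25), the growth factor receptor gene Fgfr3 (0.76 ± 0.31) and Gja1 (0.76 ± 0.39). Astrocytes use many genes of this list, and their mean share was also higher with the mimic (16.5% against 11.4%). Id3 alone passed adjusted over the list alone, and 0 passed over all genes. The camera adjusted p was 0.000372, and the adjusted p was 0.606 with an estimated correlation. Without control mouse 1, mimic mouse 2 or control mouse 5 the camera adjusted p was 0.0872, 0.159 and 0.154, with median log2 folds of 0.24, 0.13 and 0.18. Notch and BMP signalling genes were higher for 9 of 14 members (median 0.11), led by Id1 and Id3, the receptor gene Bmpr2 (1.31 ± 0.36) and the Notch target Hey1 (1.40 ± 0.50, or 2.10 without control mouse 7). In endothelial-like cells, whose mean share was higher with the mimic, 8 of 11 members were higher (median 0.58, against 0.30 over all tested genes there, adjusted p = 0.974). Adjusted over the list alone 3 passed, Id1, Id3 and Bmpr2, and 0 over all genes. The camera adjusted p was 0.0474, and the adjusted p was 0.482 with an estimated correlation. It was 0.129, 0.159, 0.226 and 0.321 without control mouse 1, mimic mouse 2, control mouse 5 and mimic mouse 8, and the median turned to -0.04 without mouse 5 and -0.22 without mouse 8. The camera adjusted p without the sort date as covariate was 0.0515. The mixed test of fry, which asks for changes in either direction, gave this list an adjusted p of 0.00331.

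Myelin genes were lower in mimic mice for 18 of 18 members (median log2 fold -0.20), such as Opalin (-0.34 ± 0.21) and the myelin lipid enzymes Ugt8a (-0.28 ± 0.23) and Fa2h (-0.19 ± 0.17). Adjusted over the list alone 0 passed, and over all genes 0. The camera adjusted p was 0.0428, and the adjusted p was 0.651 with an estimated correlation. The list lost its call without control mouse 1, mimic mouse 2, control mouse 5 or mimic mouse 8 (adjusted p = 0.167, 0.171, 0.725 and 0.0868, medians -0.13, -0.18, -0.0030 and -0.15) and without the sort date as covariate (0.0515, median -0.19). Oligodendrocyte-like cells also had a lower mean share with the mimic (41.1% against 48.3%). In these cells alone the median log2 fold of the myelin list was 0.00 (9 of 18 higher, camera adjusted p = 0.942). The other 13 lists did not pass. Neuronal differentiation genes were lower for 8 of 10 members (median -0.17, adjusted p = 0.0562, or 0.606 with an estimated correlation). The mean share of neuroblast-like cells was also lower with the mimic (4.33% against 7.35%). With wells assigned by sample titles 3 lists passed, and the medians of antigen presentation, stem cell quiescence, Notch and BMP signalling and myelin were -0.25, -0.09, -0.23 and 0.21. Antigen presentation and myelin passed there in the opposite direction (adjusted p = 0.0412 and 0.00171). Interferon response and immediate early genes then had medians of 0.0014 and 0.10 (adjusted p = 0.9754 and 0.451). Without mimic mouse 2 or control mouse 5, 3 lists passed.

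The fourth comparison follows the stem cell lineage and the published targets of miR-132. Nes had a log2 fold of 0.40 ± 0.32, Hopx 0.41 ± 0.71 (1.51 without control mouse 3), the granule neuron factor gene Prox1 -0.55 ± 0.30 and the neurotrophin receptor gene Ntrk2 0.59 ± 0.32 (edgeR adjusted p = 0.999 for each). These folds are over all kept cells and do not single out granule neurons or stem cells. Prox1 had a count in 68.3% of oligodendrocyte-like cells (mean 230 CPM), and averaged 1117 CPM in the fewer neuroblast-like cells. Nes was highest in pericyte-like cells (377 CPM). Mki67, Eomes, Dcx and Bdnf had a count in 2.97%, 5.19%, 7.12% and 0.593% of kept cells, too few for the test. Of the published targets 18 were measured, and 10 were higher in mimic mice, with a median log2 fold of 0.09 (camera adjusted p = 0.363). Rasa1, a regulator of Ras, had 0.33 ± 0.47, the GTPase regulator gene Arhgap32 -0.06 ± 0.40 and the transcription factor gene Foxo3 0.17 ± 0.30. Adjusted over the list alone 0 passed, and over all genes 0.

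The fifth comparison asks whether genes with a site for miR-132 in their 3' UTR were lower in mimic mice. In all kept cells, 272 genes with an 8-base site had a median log2 fold of -0.0017, and the matched difference from site-free genes was -0.0036 (permutation p = 0.880). Shuffled labels gave differences between -0.051 and 0.050 in 95% of permutations. With any 7-base site the difference was -0.012 over 1214 genes (permutation p = 0.400), and with at least 2 sites -0.043 over 159 genes (permutation p = 0.213). Within classes the difference for the 8-base site was 0.018 in oligodendrocyte-like cells, -0.053 in astrocyte-like cells, 0.12 in endothelial-like cells and 0.093 in pericyte-like cells (permutation p = 0.527, 0.527, 0.259 and 0.459). It was 0.054 in cluster 1 and -0.018 in cluster 2 (permutation p = 0.449 and 0.564). In pericyte-like cells it was 0.290 without mimic mouse 6 and 0.339 without mimic mouse 8 (permutation p = 0.0460 and 0.0210), and in cluster 2 it was -0.0793 without mimic mouse 4 (permutation p = 0.0300). All p of this comparison come from shuffling sites among genes, so they measure no variation between mice. Those without single mice were not adjusted for the number of such runs. With all mice, other groupings reached 0.370 in size in pericyte-like cells and 0.0940 in cluster 2.

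In oligodendrocyte-like cells, the glucocorticoid-induced kinase gene Sgk1 stood at 471 ± 156 CPM in mimic and 212 ± 62.9 CPM in control mice (n = 4 each, log2 fold 1.12 ± 0.26). Nfkbia, the inhibitor of NF-kappaB, stood at 126 ± 10.1 against 60.9 ± 24.9 CPM (1.06 ± 0.29). The mitochondrial folate enzyme gene Aldh1l2 had a log2 fold of 2.17 ± 0.49, Acap3 3.01 ± 0.74, Adgrb1 3.57 ± 0.93, Zfp945 2.51 ± 0.67 and Zdhhc4 1.60 ± 0.44. Lower in mimic mice were Timm50, of the mitochondrial import machinery (-1.0 ± 0.25), the adhesion gene Cadm4 (-1.49 ± 0.41) and Gpr17, a receptor of newly formed oligodendrocytes (-3.49 ± 0.96). Without single mice, Acap3 had 2.40 (mimic mouse 8), Adgrb1 2.40 (mimic mouse 6) and Gpr17 -4.14 and -4.17 (mimic mouse 2 and control mouse 3). Immediate early genes were higher for 12 of 15 members (median 0.67), with a camera adjusted p of 0.0585. They were higher for 13 of 16 members in cluster 1 (median 0.31), of which control mouse 7 had no cell, and for 4 of 13 in cluster 2 (median -0.072), with adjusted p of 0.262 and 0.750. edgeR called 0 of 7450 genes (lowest adjusted p 1.00, 213 at unadjusted p under 0.05, where 372 would be expected by chance). DESeq2 called 3, Acap3, Sgk1 and Aldh1l2, and camera called 0 of 14 lists (1, 1 and 2 without control mouse 1, mimic mouse 4 and control mouse 5). Without a low-count filter edgeR called 18 genes, among them C4b, H2-D1, B2m and the acute phase gene Serpina3n.

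By number, cluster 1 was tested in 3 control and 4 mimic mice, since mouse 7 had no cell of it, and cluster 2 in 4 and 4. edgeR called 0 of 6892 and 0 of 7408 genes (113 and 195 at unadjusted p under 0.05, where 345 and 370 would be expected by chance). In cluster 1, DESeq2 called 134 genes and limma on mean log values called 2, Sgk1 and Htra1. DESeq2 called 0 in cluster 2. Camera called 0 of 15 lists in cluster 1 (1 without control mouse 1) and 0 of 14 in cluster 2 (1 without mimic mouse 8).

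In astrocyte-like cells, mitochondrially encoded genes were lower in mimic mice for 13 of 13 measured members (median log2 fold -0.56, against 0.21 over all tested genes). Cluster 6 gave 16 of 37 control and 16 of 58 mimic cells of this class, and cluster 8 the others. The ribosomal RNA genes mt-Rnr1 and mt-Rnr2 had log2 folds of -0.76 ± 0.27 and -0.64 ± 0.25, and mt-Co1 and mt-Cytb, of the respiratory chain, -0.56 ± 0.27 and -0.44 ± 0.22. Adjusted over the list alone 0 passed, and over all genes 0. The camera adjusted p was 0.00145, and the adjusted p was 0.685 with an estimated correlation. Without control mouse 5 or mimic mouse 6 the camera adjusted p was 0.135 and 0.0623 and 0 lists passed, and without control mouse 1 or mimic mouse 2, 2 lists passed. With wells assigned by sample titles the median was -0.13 (adjusted p = 0.847). The 10 genes of smallest p were found in 10.5% to 17.9% of cells and nearly absent from control mice. In 215 genes, 2.87% of those tested in this class, the groups did not overlap, against 2.86% by chance. The antisense transcript 9530082P21Rik, the glycosyltransferase gene B3gat3 and the BMP modulator gene Twsg1 had 0 counts in control mice and 2037, 1666 and 1036 in mimic mice. Against a floor of 3 counts over the group, scaled to total counts, the ratios were 400.0, 327 and 203. Reads of a cell are not independent, so these ratios set no lower limit on the difference. The model log2 fold of Twsg1 was 10.37, and 9.75 and 11.02 without control mice 3 and 7. Slc6a8, Col16a1 and 8430429K09Rik had 2 counts each in controls, Ccdc114, Gng7, Wdr24 and Pold2 had 5, 6, 8 and 31, and in mimic mice these 7 genes had 529 to 3013. edgeR called 0 of 7480 genes (lowest adjusted p 1.00, 122 at unadjusted p under 0.05, where 374 would be expected by chance), and DESeq2 called 31. Without a low-count filter edgeR called 2 genes, both lower, mt-Rnr2 and the ribosomal RNA gene Rn18s-rs5.

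In endothelial-like cells, tested in 3 control and 4 mimic mice, Sox17 stood at 783 ± 37.9 CPM with the mimic (n = 4) and 353 ± 91.0 CPM with the control oligonucleotide (n = 3), a log2 fold of 1.16 ± 0.31. It had a count in 68.2% of these cells. Antigen presentation genes were higher for 8 of 9 members (median 0.75, against 0.30 over all tested genes), among them B2m (0.66 ± 0.29), H2-D1 (0.94 ± 0.41) and H2-K1 (0.65 ± 0.34), with a camera adjusted p of 0.110. Tnip2, Cbl, Zfp871, Tmem39a and Rsrc1 had 0 counts in the 3 control mice, and had counts in 12.1% to 18.7% of these cells. Against the same floor their ratios in mimic mice were 562, 504, 783, 587 and 205, which again set no lower limit. The model log2 fold of Tmem39a was 12.37, and 11.07 without mimic mouse 8. The circadian repressor gene Cry2, Napg and Ndst1 had 2, 2 and 1 counts in controls against 4187, 827 and 2987 in mimic mice, and the semaphorin receptor gene Plxna1 had 5 against 244. In 361 genes, 6.05% of those tested in this class, the groups did not overlap. The chance share of 2.86% holds for 4 against 4 mice, not for 3 against 4. With the looser cell filter Ndst1 turned direction and was lower in mimic mice. edgeR called 0 of 5971 genes (lowest adjusted p 0.999, 122 at unadjusted p under 0.05, where 299 would be expected by chance). DESeq2 called 37, and camera called 0 of 14 lists (1 without mimic mouse 2). With wells assigned by sample titles Sox17 had a log2 fold of -1.04 here.

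In pericyte-like cells, the plexin gene Plxnb2 stood at 305 ± 63.2 CPM in mimic and 881 ± 222 CPM in control mice (n = 4 each, log2 fold -1.53 ± 0.37). Tns2, a focal adhesion protein gene found in 94.4% of these cells, had -1.08 ± 0.28, the planar polarity gene Prickle2 -2.35 ± 0.71 and Mum1 5.80 ± 1.43 (6.71 without control mouse 7). Against a floor of 3 counts over the group, control counts gave ratios of 976, 838, 531, 488, 389 and 596 for Myg1, Fam136a, Adam17, 2700046A07Rik, Saa1 and Tipin. These ratios set no lower limit, since reads of a cell are not independent. The genes had 0 counts in mimic mice and had counts in 11.3% to 14.1% of pericyte-like cells. Their model log2 folds moved from -12.17 to -11.00 for Tipin without control mouse 5 and from -11.46 to -10.86 for Saa1 without control mouse 3. Without control mouse 7 they moved from -12.24 to -11.61 for Fam136a and from -11.28 to -10.64 for 2700046A07Rik. In 129 genes, 2.53% of those tested in this class, the groups did not overlap, against 2.86% by chance. edgeR called 0 of 5105 genes (lowest adjusted p 1, 36 at unadjusted p under 0.05, where 255 would be expected by chance). DESeq2 called 15, and camera called 0 of 15 lists.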

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

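The tests of the immune genes, of the well maps, of mouse 7 and of other groupings of the mice were chosen after the results were seen, the map test excepted, and the predictions for mouse 7 and for chance in the immune genes were written before their values.

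In groups of 4 mice, 13 of 198 groups held a mouse far from the other 3 by Dixon's rule for gap over range. For 6 of the 13, genes chosen for near-absence from controls, a single control mouse held all counts, which makes the value 1 by construction, so the number of groups was not set against chance. Pericyte-like cells made up 22.0% of control mouse 7 (18 of 82 cells, Wilson 95% interval 14.4% to 32.1%) and 6.76% to 8.99% of the other controls (gap over range 0.853). Smooth muscle-like cells made up 4% of mimic mouse 4 (3 of 75 cells, Wilson 95% interval 1.37% to 11.1%) and 1.09% to 1.16% of the other mimic mice (0.974). In oligodendrocyte-like cells Gpr17 stood at 1.31 CPM in mimic mouse 2 and at 0.332 to 0.459 CPM in the other mimic mice (0.870). In astrocyte-like cells, control mouse 7 held all control counts of Slc6a8 (gap over range 1) and control mouse 3 all those of Col16a1, 8430429K09Rik, Wdr24, Ccdc114 and Gng7 (1 for each). Pold2 stood at 4.99 CPM in control mouse 7 and at no more than 0.361 CPM in the other controls (0.928). In endothelial-like cells Cbl stood at 211 CPM in mimic mouse 4 and at 41.9 to 62.0 CPM in the other mimic mice (0.881). In all kept cells Mt1 was lowest in control mouse 1 with 264 CPM, against 419 to 431 CPM (0.927), and Hey1 was highest in control mouse 7 with 65.3 CPM, against 11.4 to 16.5 CPM (0.905).

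Antigen presentation and interferon response genes were higher with the mimic in all kept cells (18 of 18 members, median log2 fold 0.798). If more endothelial-like cells were the cause, the difference should be absent within another class, but 8 of 8 members were higher in oligodendrocyte-like cells (median 0.653), a value that other groupings of the mice also reach (highest 0.968), so this cannot be told. In the remaining classes 27 of 30 members were higher in endothelial-like (median 0.601, against 0.304 over all tested genes), 7 of 11 in astrocyte-like (0.0793, against 0.205) and 7 of 15 in pericyte-like cells (-0.181). The 16 wells of many genes do not account for it, since the median was 0.767 without them. Of 34 groupings of the mice, the real one included, 4 gave a median as large for both lists together (highest 0.945). Chance therefore cannot be excluded for the lists together, and an effect of the mimic was not separated from it.

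The labels give 2 maps from wells to mice, and directions of many results depend on the choice. If wells followed the sample titles, class counts were predicted to differ between the mice of that map, but the permutation p was 0.892 with labels permuted within index runs. Mice alike in class counts would also give a large p, so this does not exclude the title map. For the description map, with labels permuted over all cells, the permutation p was 1.00e-05, the smallest that the permutations allow. The 2 maps were permuted in different ways, so their p are not directly comparable. Each mouse of that map had 2 wells of many genes, against 0 to 8 per mouse of the title map. Wells with under 5000 counts numbered 2 to 3 per mouse, against 0 to 5 in the title map. At the first limit of 1000 counts they numbered 0 to 2 per mouse of the description map and 0 to 3 of the title map. Near-empty wells therefore did not tell the maps apart at the first limit, and both limits were set after seeing the data. The mice of the description map are also runs of the index numbers, so an effect of handling by run would look the same, and no biological explanation was tested.

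Control mouse 7 had 0 of 22 oligodendrocyte-like cells in cluster 1, against 19.6% to 35.7% of those cells in the other mice. Shallow sequencing does not account for it, since these cells had a median of 851826 counts (624901 to 871628 in the others). A weaker immediate early response in all cells of that mouse may account for it: the mean of the list in endothelial-like cells was 2.43 (3.75 to 6.24 in the others), though in astrocyte-like cells mouse 7 was second lowest. Whether handling or biology lowered it was not tested.

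The mice were grouped in 34 ways, the real one included in each count that follows. Unlike the real one, some were unbalanced over the sort dates. Chance could not be excluded for the number of lists that passed or for the seed site differences. Of the lists that passed in all kept cells, interferon response alone had a median no other grouping reached (0.775, highest other 0.738), not adjusted over lists. Groupings as large were 3 for immediate early genes, 4 for antigen presentation, 14 for myelin, 15 for stem cell quiescence and 27 for Notch and BMP signalling. In astrocyte-like cells, the median of mitochondrially encoded genes was 0.560 in size (highest other 0.706, 7 groupings as large). Where the real count was 0, every grouping is as large by construction and the comparison tests nothing. In all kept cells 0 genes were called in the real grouping (highest other 1, 34 groupings as large), 6 lists passed (highest other 10, 7 as large) and the seed site difference was 0.00362 in size (highest other 0.0624, 32 as large). For genes, 34 groupings were as large in each class (real 0), with a highest other of 1 in cluster 1 and 0 in oligodendrocyte-like, astrocyte-like, endothelial-like and pericyte-like cells and cluster 2. For lists, 9 were as large in astrocyte-like cells (real 1, highest other 2) and 34 in each other class (real 0), with a highest other of 2 in oligodendrocyte-like and endothelial-like cells and clusters 1 and 2, and 1 in pericyte-like cells. Seed site differences were 0.0184 in oligodendrocyte-like (highest other 0.0516, 20 as large), 0.0527 in astrocyte-like (0.182, 16 as large), 0.121 in endothelial-like (0.242, 6 as large) and 0.0927 in pericyte-like cells (0.370, 21 as large). They were 0.0542 in cluster 1 (0.252, 18 as large) and 0.0184 in cluster 2 (0.0940, 24 as large).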

How the results depend on the processing

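All alternatives were planned before the data were examined, except leaving out the wells of many genes and permuting shares within sort dates. Both of these were chosen after seeing the data. No gene was called by edgeR with other scalings, covariates or cell filters, and the counts that moved are given next. The cause was not tested for any result that did not keep its call or direction. Few cells per mouse limit the single classes: astrocyte-like, endothelial-like and pericyte-like cells and cluster 1 had no gene test with at least 10 cells per mouse, and endothelial-like and pericyte-like cells none with the stricter cell filter. Clusters by number had none with other cell filters or clusterings, endothelial-like cells none new without mouse 1 and cluster 1 none new without mouse 7. Of the values not listed here, 230 of main results and 1175 of single genes or lists kept direction and side of the threshold, while 48 of single genes or lists newly passed it and 5 no longer did. With single mice left out, 213 and 680 kept both.

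With wells assigned by sample titles, log2 folds in all kept cells turned for Sox17 -1.17, Vwa1 -0.47, Gpcpd1 -0.25, Spock2 -0.47, Agrn -0.46, Sec24d -0.89, Parva -0.15, Sgms1 -0.12, Nes -0.31, Hopx -0.0934, Prox1 0.12, Arhgap32 0.32, Foxo3 -0.36, Id3 -0.23, Mt1 -0.15, Fgfr3 -0.32, Bmpr2 -0.20, Hey1 -0.24, Ifitm3 -0.0256, H2-D1 -0.21, B2m -0.25, Psmb8 -0.62, Zfp36 -0.0824, Opalin 0.14, Ugt8a 0.22 and Fa2h 0.24. In oligodendrocyte-like cells they turned for Aldh1l2 -1.30, Timm50 0.00696, Acap3 -0.31, Adgrb1 -1.38, Zfp945 -0.60, Cadm4 0.14 and Nfkbia -0.11. In astrocyte-like cells they turned for Slc6a8 -1.68, 9530082P21Rik -0.14, Col16a1 -4.57, Pold2 -2.31, Wdr24 -4.81, Ccdc114 -4.43, Twsg1 -0.24 and mt-Co1 0.00323. In endothelial-like cells they turned for Cry2 -1.37, Tnip2 -1.16, Tmem39a -2.35 and Sox17 -1.04. In pericyte-like cells they turned for Myg1 0.80, Plxnb2 0.54, Mum1 -2.11, Adam17 0.59, 2700046A07Rik 0.52, Saa1 0.75 and Prickle2 0.10. Median log2 folds of lists in all kept cells were -0.0934 for stem cell quiescence, -0.23 for Notch and BMP signalling, -0.25 for antigen presentation and 0.21 for myelin, with 3 lists past the threshold there and 0 in astrocyte-like cells. Seed site differences were -0.0395 in endothelial-like cells, -0.309 in pericyte-like cells (permutation p = 0.0120) and 0.000827 in cluster 2. Differences in quality were -12.9 genes per cell, 0.0182 points of mitochondrial counts and 0.0960 points of 18S RNA. Shares differed by -1.73 points for astrocyte-like, -1.88 for endothelial-like, 4.92 for oligodendrocyte-like, 0.791 for neuroblast-like and -0.946 for oligodendrocyte precursor-like cells, 4.58 for cluster 2 and -1.59 for cluster 8.

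DESeq2 called 12 genes in all kept cells, 3 in oligodendrocyte-like, 31 in astrocyte-like, 37 in endothelial-like and 15 in pericyte-like cells and 134 in cluster 1. Without a low-count filter edgeR called 84, 18, 2 and 4 in the first 4 of these, 5 in cluster 1 and 16 in cluster 2. limma on mean log values called 2 in cluster 1 and gave Nes -0.0332. Camera with an estimated correlation passed 0 lists in all kept cells and 0 in astrocyte-like cells, and fry 0 and 0, while its mixed test passed 1 list in all kept cells, Notch and BMP signalling. With the looser filter Ndst1 had -3.48 in endothelial-like cells.

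The seed site difference was 0.000953 in all kept cells without the sort date. With at least 2 sites it was -0.00152 in oligodendrocyte-like cells, -0.143 in cluster 1 and 0.0161 in cluster 2. With any 7-base site it was -0.00358 in cluster 1 and 0.00750 in cluster 2. Smooth muscle-like shares differed by 0.113 points with the looser filter, 0.0497 without a mitochondrial limit and 0.0497 with fewer variable genes. Within plate L8, shares differed by -0.691 points for astrocyte-like, 0.952 for oligodendrocyte-like and 0.110 for smooth muscle-like cells. Within plate L7 they differed by 0.440 for fibroblast-like and -0.619 for oligodendrocyte precursor-like cells, -4.72 for cluster 1 and 3.20 for cluster 6. Within 17 April they differed by 1.63 for fibroblast-like and 0.858 for smooth muscle-like cells, -4.74 for cluster 1 and 1.96 for cluster 6. Within 19 April they differed by 0.370 for neuroblast-like and -0.0808 for oligodendrocyte precursor-like cells.

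Leaving out each mouse in turn gave log2 folds of -0.40 to 0.25 for Arhgap32, -0.0661 to 0.62 for Rasa1 and a median of -0.22 to 0.41 for Notch and BMP signalling. Without a change of sign, it moved folds by over 1.5 times for 5 named genes in all kept cells, 3 in oligodendrocyte-like, 8 in astrocyte-like, 5 in endothelial-like and 5 in pericyte-like cells. The number of lists past the threshold was 3 to 9 in all kept cells, 0 to 2 in oligodendrocyte-like, 0 to 2 in astrocyte-like and 0 to 1 in endothelial-like cells, 0 to 1 in cluster 1 and 0 to 1 in cluster 2. It was 3 in all kept cells without mimic mouse 2 or control mouse 5. Seed site differences were -0.0266 to 0.0334 in all kept cells, -0.0216 to 0.0273 in oligodendrocyte-like, -0.0733 to 0.0857 in astrocyte-like and -0.0168 to 0.339 in pericyte-like cells, -0.0424 to 0.108 in cluster 1 and -0.0793 to 0.0164 in cluster 2. Share differences were -0.974 to 0.652 points for fibroblast-like, -0.114 to 0.853 for oligodendrocyte precursor-like, -3.60 to 1.49 for pericyte-like and -0.946 to 0.714 for smooth muscle-like cells, -3.14 to 3.23 for cluster 1 and -2.06 to 0.838 for cluster 6.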

Other observations

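The tests by sort date and of the many-gene wells were chosen after the results were seen.

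No marker set passed adjustment between sort dates in the many-gene wells. Summed pericyte markers there stood at 9139 ± 1883 CPM on 19 April and 2124 ± 1198 CPM on 17 April (SD, n = 4 mice each, exact permutation p = 0.0286, adjusted 0.171 over 6 marker sets), and endothelial markers at 4079 ± 975 and 2287 ± 1079 CPM (exact p = 0.0571, adjusted 0.171). Microglial markers stood at 47.1 ± 7.45 CPM in control and 63.6 ± 19.4 CPM in mimic mice (n = 4 each, exact p = 0.171). The 16 wells held 10045 to 11362 genes each, where the next highest kept well had 5015, and there were 2 per mouse. In these wells Vtn averaged 3852 CPM, Cldn5 1004 CPM and Aldoc 892 CPM. Between dates, edgeR called 0 genes in all kept cells (916 at unadjusted p under 0.05, where 441 would be expected by chance). Adgrf5, Slco1a4 and Egfl7, genes of brain endothelium, were among the smallest p.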
